A study of Mus musculus with 6 samples.

How the data were processed

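Gene expression was measured in skin from 6 mouse samples on single-channel Affymetrix arrays with biotin-labelled targets, 1 array per sample. Total RNA had been extracted with TRIzol, per the labels' protocols. The labels give 3 wild-type and 3 knock-in samples on a C57BL/6 background. They give the knock-in a genotype code, but they do not name the gene that was changed. They give no sex, age, body site, hybridisation date or treatment, and they do not say that the samples came from separate animals. The p-values therefore measure only the spread between these 6 samples.

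The deposited table holds 1 linear signal intensity per probe set and array, made with the MAS5 algorithm per the submitters' processing notes. The version and settings are not given in the sources used here. MAS5 subtracts a mismatch-based background and scales each array by 1 factor. In the deposited intensity values the 2% trimmed mean of every array was 150, so the arrays were already scaled to a common level, and no further normalization was applied in the main analysis. A single factor per array leaves any change in the shape of the distribution in place. The table has no detection calls, so no probe set was called absent.

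The table holds 45101 probe sets, of which 64 are controls and were left out of all tests across genes. In the platform annotation, 34945 probe sets have 1 gene symbol, 932 have several and 9160 have none. Probe sets with several symbols or none named no gene. By gene ID, 34741 probe sets were matched to the RefSeq gene table of assembly GRCm38.p6, and 0 symbols changed. Coordinates are not printed because no build is named with the arrays. Where a gene had several probe sets, the one with the highest mean over the 6 arrays stood for it. The 18193 genes were reduced to 11670 by keeping those above the array's own median on at least 3 arrays, which left out 6523 dim genes. Genes of the Krtap, Sprr, Stfa, Saa and Chil families are near-identical in sequence, so a probe set of one member may also read another.

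Signals were tested as log2(signal + 16) with limma 3.58.1 in R 4.3.3, by lmFit and eBayes with a mean-variance trend and a two-sided test. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Differences are knock-in minus wild-type on the log2(signal + 16) scale. The offset of 16 understates the change of dim genes, so folds of genes with a signal near 16 or below in either group are too small. With an offset of 1 or 64 in its place, the log2 differences of Ccl3, Il6, Tnfsf11, Nkg7, Cd207, S100a7l2, Gm13306 and Uty moved by over 1.5 times in both cases, and with 64 also those of Alas2, Hba-a2, Gsta2, Cd3g, Hamp2 and Kdm5d. Errors of signals are SDs (n = 3) and errors of log2 differences are standard errors. The median standard error of a log2 difference was 0.13, and the small number of arrays limits the precision.

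Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, two-sided and adjusted over all 42 lists. Camera compares a list with all other genes. The same lists were tested with a correlation estimated from the data, and with fry, which tests whether the genes of a list move on balance in one direction. Members past the threshold were counted over all genes tested and again adjusted over the list alone. The lists hold 774 measured genes, of which 27 are in more than 1 list. Some genes on the lists have no probe set listed for them and were not analysed here. Others fell below the filter on dim probe sets and were left out of the counts and tests, so a list's measured genes can be a small part of it. The groups, the test, the filter, the offset, the lists, the alternatives and the rule for named genes were set before the data were examined. By that rule the text names the 12 genes with the largest difference in each direction whose 3 knock-in values all lay on one side of the 3 wild-type values. From each list it also names up to 4 members with the smallest unadjusted p. A few other genes, named as such in the text, were chosen after their values were seen.

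The procedure was tested on simulated arrays with the spread of the knock-in and wild-type comparison, run on 11462 genes. It recovered 44% of genes simulated with a log2 difference of 0.5, 96% of those at 1, and 100% of those at 2 and at 4. Of 193 calls, 12 (6.22%) were false. A list shifted by 0.4 was recovered, and 0 of the other lists were called. Besides that list 200 genes were changed, and the simulated genes varied independently of each other. In the real arrays the estimated correlation within the hair shaft list, for example, was 0.834. The simulation therefore does not test list calls where the genes of a list vary together. The alternatives were another offset, other filters on dim probe sets, quantile normalization, median centring, another variance prior and array weights. Further alternatives were the mean over probe sets, leaving out probe sets shared between transcripts, the replicate number as a block, and leaving out each array in turn. Leaving out the X- and Y-linked genes was added after the data were seen.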

Results

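Skin RNA from 3 wild-type and 3 knock-in samples was compared on 6 arrays. Replicates resembled each other closely. On the log2 scale, over the genes tested, Pearson's r lay between 0.975 and 0.983 within wild-type and between 0.979 and 0.985 within knock-in. Between the groups it lay between 0.880 and 0.917, and the first principal component, with 78.4% of the variance, separated the groups. The ratios of 3' to 5' probe sets, a sign of RNA integrity, were 1.24 ± 0.0358 and 1.23 ± 0.0385 (SD, n = 3) for actin in wild-type and knock-in. For Gapdh they were 0.625 ± 0.0306 and 0.649 ± 0.0258. The 5' control for 18S ribosomal RNA, by contrast, gave a signal of 1848 ± 493 in wild-type and 481 ± 301 in knock-in. The middle 18S control gave 1378 ± 350 and 652 ± 255. Neither overlapped between the groups (two-sided exact permutation p = 0.1 for each, the smallest that 3 against 3 allows). The 3' control for 18S gave means of 399 and 265 and overlapped between the groups.

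The comparison asks which transcripts of the skin differ between the wild-type and knock-in arrays. All 3 wild-type arrays carried Y-linked signal and all 3 knock-in arrays carried Xist, a transcript of the inactive X chromosome. A difference of sex therefore cannot be told apart from one of genotype in any result below. With camera at a preset inter-gene correlation, lists of antimicrobial, neutrophil and wound response genes were higher in knock-in, and lists of hair shaft, melanocyte and MHC class II genes lower. With an estimated correlation camera called 0 of the 42 lists, 6 had an unadjusted p under 0.05, and fry called 21. Chil3, a chitinase-like protein of myeloid cells (probe set 1419764_at), rose from a signal of 13.6 ± 1.05 to 4655 ± 1939 (SD, n = 3 per group), a log2 difference of 7.21 ± 0.27 (limma, Benjamini-Hochberg adjusted p = 1.39e-06). The neutrophil-attracting chemokine Cxcl2 (1449984_at) rose from 12.7 ± 2.50 to 3439.7 ± 916, a log2 difference of 6.88 ± 0.19 (adjusted p = 2.37e-07). In the other direction, Krtap19-1, a keratin-associated protein of the hair fibre (1427801_at), fell from 5244 ± 957 to 477 ± 193, a log2 difference of -3.49 ± 0.29 (adjusted p = 1.05e-04), or -2.28 with the mean over its probe sets.

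Of 11670 genes tested, 3625 (31.1%) passed the threshold, 1725 higher and 1900 lower in knock-in. At an unadjusted p under 0.05 there were 4983 genes. A difference of at least 2-fold was reached by 952 of the genes past the threshold, 487 higher and 465 lower, and one of at least 8-fold by 54 higher and 13 lower. The groups did not overlap for 5485 genes (47.0%), where chance gives 10%. The median log2 difference of all genes was -0.02. Without wild-type replicate 3, 2369 genes passed, 1154 higher, with genes lower in knock-in falling to 1215.

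Among the 12 genes with the largest increases, Saa3 (1450826_a_at), an acute-phase protein, rose from 79.9 ± 8.62 to 9082 ± 2251, a log2 difference of 6.54 ± 0.18. Lcn2 (1427747_a_at), which binds bacterial siderophores, rose by 5.97 ± 0.26, and S100a9 (1448756_at), a subunit of calprotectin, by 5.72 ± 0.19. Prg4 (1449824_at), the lubricant proteoglycan lubricin, went from 60.1 ± 10.9 to 5034 ± 1779, a log2 difference of 5.99 ± 0.25. Saa1 (1419075_s_at), Clec4d (1420804_s_at), Cxcl3 (1438148_at), the collagenase Mmp13 (1417256_at) and Ccl3 (1419561_at) had log2 differences of 4.98, 4.87, 4.84, 4.79 and 4.71, with adjusted p between 4.19e-06 and 1.75e-04. Among the 12 with the largest decreases, Defb8 (1427778_at), a beta-defensin, fell from 484 ± 144 to 18.9 ± 0.887 (-3.80 ± 0.19), and Pvalb (1417653_at), the calcium buffer of fast muscle fibres, from 4528 ± 1489 to 401 ± 57.4 (-3.40 ± 0.21). Krtap5-2 (1420452_at), Krtap6-3 (1427842_at) and Krtap19-4 (1426203_at) had log2 differences of -3.37, -3.27 and -3.02. Gm13306 (1457324_at), S100a7l2 (1445608_at) and Hamp2 (1436643_x_at) had differences of -3.35, -3.28 and -3.02, and their signals in knock-in were 5.63 ± 6.67, 6.27 ± 3.69 and 13.1 ± 9.58.

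**Figure D1:**
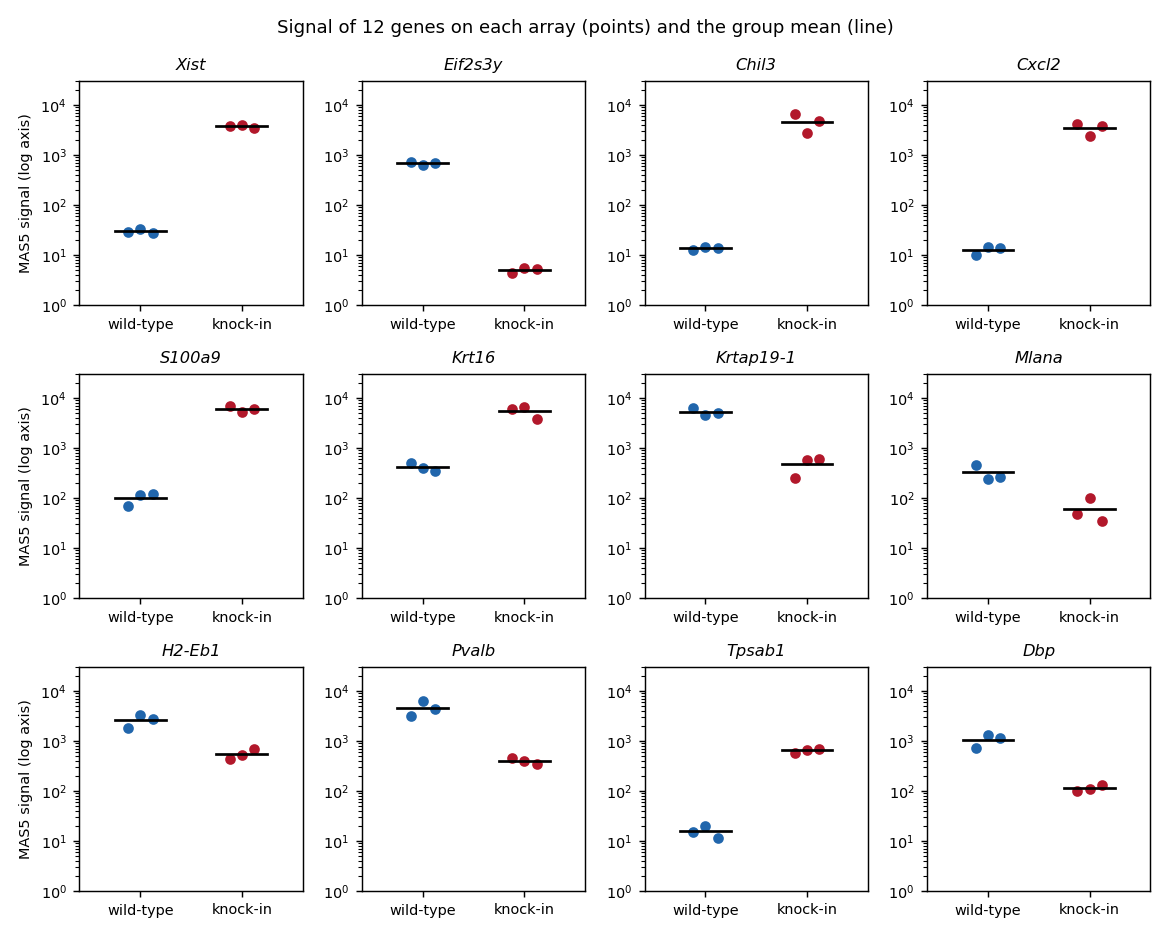
MAS5 signal of 12 genes on a log axis, with 1 point per array (3 wild-type in blue, 3 knock-in in red) and a line at each group mean. Each gene separates the groups, with Chil3 at mean signals of 13.6 and 4655, and Eif2s3y at 687 and 5.04.

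Genes that mark the sex chromosomes separated the groups completely. Xist (1436936_s_at), the RNA that coats the inactive X chromosome, had mean signals of 29.7 ± 2.44 on the wild-type arrays and 3729.7 ± 282 on the knock-in arrays, a log2 difference of 6.36 ± 0.10 (adjusted p = 8.24e-09). The Y-linked genes Eif2s3y (1417210_at), Uty (1426598_at) and Kdm5d (1424903_at) fell from mean signals of 687 ± 42.6, 195 ± 34.3 and 197 ± 1.49 to 5.04 ± 0.544, 2.21 ± 2.60 and 5.97 ± 1.34, with log2 differences of -5.06, -3.53 and -3.28. The sex-linked list had 4 measured genes, 1 higher and 3 lower over all genes tested and when adjusted over the list alone. This list joins Xist with Y-linked genes, which differ between the sexes in opposite directions. The direction of the list therefore reflects only how many of each it holds. Its median log2 difference was -3.41 (-5.53 with an offset of 1 and -1.93 with 64) and its mean -1.38 (camera adjusted p = 0.0288, and adjusted p = 0.258 with an estimated correlation). With an offset of 1 the camera adjusted p was 0.0565, and with a stricter filter 0.066, in a range from 4.82e-05 with fry to 0.258 with an estimated correlation over 19 alternatives. With camera at the preset correlation the range was from 0.00353 to 0.066. All 3 wild-type arrays carried Y-linked signal and all 3 knock-in arrays carried Xist, so genotype and this pattern coincide on every array. This limit holds for every gene and list of this report, and for the lower signal of the 5' and middle 18S controls in knock-in. None of these differences can be assigned to genotype rather than to a difference of sex. With the X- and Y-linked genes left out, an alternative chosen after the data were seen, 3513 genes passed.

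Lists of inflammatory genes were higher in knock-in. Of 22 antimicrobial and alarmin genes, 19 rose, 2 fell and 1 did not pass (18 to 19 rose and 1 to 2 fell with an array left out), and adjusted over the list alone, 19 passed higher and 2 lower. Besides those above, Slpi, a protease inhibitor of inflamed epithelia, went from 89.1 ± 8.26 to 1852 ± 132, a log2 difference of 4.15 ± 0.10. The antimicrobial list had a median log2 difference of 2.51 (camera adjusted p = 9.75e-15, and adjusted p = 0.137 with an estimated correlation), and its median was 3.79 with an offset of 1, 1.38 with 64 and 4.11 with a stricter filter. Of 12 neutrophil genes, 11 rose, 0 fell and 1 did not pass, and adjusted over the list alone, 11 passed higher and 0 lower. They included the collagenase Mmp8 (4.55), Stfa2l1 (3.78) and Hdc (3.96), a histamine-forming enzyme that mast cells also make. Neutrophil genes had a median log2 difference of 2.41 (camera adjusted p = 2.89e-10, and adjusted p = 0.236 with an estimated correlation), and their median was 3.76 with a stricter filter. Among 22 chemokines and cytokines, 12 rose, 0 fell and 10 did not pass (11 to 13 rose and 0 to 3 fell with an array left out), and adjusted over the list alone, 13 passed higher and 2 lower. Il1b rose from 49.0 ± 3.75 to 1161 ± 130.4 (4.17 ± 0.11), Il6 by 3.74 ± 0.22, and the B cell chemokine Cxcl13 by 3.63 ± 0.17. Chemokine and cytokine genes had a median log2 difference of 0.74 (camera adjusted p = 2.15e-05, and adjusted p = 0.382 with an estimated correlation). The filter on dim probe sets kept 22 of the 40 on the array, and the median was 0.07 without it and 1.40 with a stricter one.

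Known targets of the transcription factor NF-kB rose in part. Of 30 measured targets, 17 rose, 2 fell and 11 did not pass (14 to 17 rose and 1 to 2 fell with an array left out), and adjusted over the list alone, 19 passed higher and 2 lower. Il1b, Cxcl2 and the prostaglandin synthase Ptgs2 (3.95 ± 0.11) were among the targets that rose, as was Cxcl1 (3.97 ± 0.17). NF-kB targets had a median log2 difference of 0.56 (camera adjusted p = 2.45e-07, and adjusted p = 0.258 with an estimated correlation). Of 17 members of the pathway itself, 6 rose, 0 fell and 11 did not pass, and adjusted over the list alone, 6 passed higher and 0 lower. Without wild-type replicate 2 or knock-in replicate 3, 3 rose, and without wild-type replicate 1, 1 fell. The ligand Tnfsf11 rose by 2.44 ± 0.18, the adaptor Myd88 by 0.63 ± 0.09 and the receptor Tnfrsf1a by 0.65 ± 0.13. Ltbr had a log2 difference of 0.39 ± 0.10 (adjusted p = 0.0223) that did not pass without wild-type replicate 2 (0.0561) or 3 (0.061), or without knock-in replicate 2 (0.0623) or 3 (0.087), in a range from 0.0178 to 0.0870 over 19 alternatives. Pathway members had a median log2 difference of 0.29 (camera adjusted p = 0.0139, and adjusted p = 0.432 with an estimated correlation). With a stricter filter on dim probe sets their camera adjusted p was 0.204, in a range from 0.00384 to 0.432 with an estimated correlation over 20 alternatives.

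Lists of stress keratins, wound response and basal keratinocyte genes were higher, while the suprabasal and cornified envelope lists did not pass. Of 19 stress keratin and small proline-rich genes, 14 rose, 1 fell and 4 did not pass (13 to 15 rose and 0 to 2 fell with an array left out), and adjusted over the list alone, 14 passed higher and 1 lower. Krt16, a keratin of wounded and hyperproliferative epidermis, rose from 409 ± 78.9 to 5371 ± 1481 (3.64 ± 0.21), Sprr1b from 389 ± 125 to 3112 ± 367 (3.00 ± 0.22) and Sprr2d by 3.10 ± 0.20. The stress keratin list had a median log2 difference of 1.76 (camera adjusted p = 1.02e-07, and adjusted p = 0.258 with an estimated correlation). Of 18 protease and wound response genes, 15 rose, 1 fell and 2 did not pass (14 to 17 rose and 0 to 1 fell with an array left out), and adjusted over the list alone, 15 passed higher and 1 lower. Tnc, a matrix protein of healing wounds, rose from 230.5 ± 30.4 to 3433 ± 692 (3.79 ± 0.16) and the urokinase receptor Plaur by 2.79 ± 0.16. Protease and wound response genes had a median log2 difference of 1.80 (camera adjusted p = 6.76e-11, and adjusted p = 0.178 with an estimated correlation). Of 15 basal keratinocyte genes, 8 rose, 0 fell and 7 did not pass, and adjusted over the list alone, 8 passed higher and 0 lower. The basement membrane genes Col7a1 and Lama3 rose by 1.81 ± 0.20 and 1.73 ± 0.20, and the integrin Itga6 by 1.06 ± 0.11. Basal keratinocyte genes had a median log2 difference of 0.52 (camera adjusted p = 4.57e-05, and adjusted p = 0.258 with an estimated correlation). The suprabasal list did not pass, with 2 higher and 3 lower of 15 (2 and 3 when adjusted over the list alone, camera adjusted p = 0.365), and held Mt4 (-1.90), Dsg1a (-1.06) and Calm4 (0.67), where Calm4 did not pass without wild-type replicate 3 (adjusted p = 0.0512) or knock-in replicate 1 (0.0538), in a range from 0.00821 to 0.0538 over 19 alternatives. Without wild-type replicate 3 or knock-in replicate 1 the suprabasal list counted 0 higher, and without wild-type replicate 1 or 2 or knock-in replicate 2 it counted 1. Cornified envelope genes did not pass either (camera adjusted p = 0.127). They counted 4 higher and 8 lower of 27 (4 and 8 when adjusted over the list alone). Of these, Tgm3 (-1.46), Scel (-0.86) and Cdsn (-0.65) fell and Rptn (0.85) rose. That list passed without wild-type replicate 3 (camera adjusted p = 0.0439), without knock-in replicate 1 (0.00169), after quantile normalization (0.0212) and without shared probe sets (0.0477), in a range from 0.00169 to 0.821 with an estimated correlation over 20 alternatives. It counted 2 higher without wild-type replicate 3 or knock-in replicate 1 or 3. Its lower members numbered 4 without wild-type replicate 3, and 12, 5 and 3 without knock-in replicate 1, 2 and 3. Skin lipid barrier genes did not pass (camera adjusted p = 0.513). They counted 7 higher and 6 lower of 22 (8 and 6 when adjusted over the list alone). Among them, Degs2 (1.25) and Sptlc3 (0.99) rose, while Lipm (-1.26, or -0.76 without shared probe sets) and St14 (-0.98) fell. EGFR ligands and receptors did not pass (camera adjusted p = 0.961). They counted 4 higher and 5 lower of 16 (5 and 6 when adjusted over the list alone). In the EGFR list, the ligand Epgn rose (2.77). The ligand Btc (-1.50) and Egfr itself (-0.68, or -0.39 with the mean over its probe sets) fell. The median of the EGFR list (-0.09, from -0.15 to -0.05 with an array left out) and its mean (0.10) differed in sign.

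Lists of hair shaft, follicle regulator, Notch and Wnt, and melanocyte genes were lower in knock-in. All 46 measured genes of the hair shaft and inner root sheath fell, also when adjusted over the list alone. Krtap5-4 fell from 959 ± 363 to 105 ± 12.2 (-2.94 ± 0.25), Krtap5-1 from 1748 ± 630.4 to 252 ± 88.3 (-2.70 ± 0.29) and Krtap9-3 from 4521 ± 936 to 888 ± 292 (-2.36 ± 0.24). Hair shaft genes had a median log2 difference of -1.80 (camera adjusted p = 3.53e-20, and adjusted p = 0.379 with an estimated correlation). Of 26 follicle regulators and stem cell genes, 2 rose, 20 fell and 4 did not pass, and adjusted over the list alone, 2 passed higher and 21 lower. The stem cell genes Lgr5 and Lhx2 fell from 394 ± 27.1 and 558 ± 61.7 to 126 ± 28.5 and 158 ± 51.4 (-1.55 ± 0.15 and -1.76 ± 0.20), and Gata3, a regulator of the inner root sheath, had a difference of -1.04 ± 0.11. Among the 4 that did not pass over all genes tested were the stem cell genes Cd34 (-0.26), Lgr6 (-0.39) and Nfatc1 (0.12), named after their values were seen. Follicle regulators had a median log2 difference of -1.06 (camera adjusted p = 2.45e-07, and adjusted p = 0.258 with an estimated correlation). Of 28 Notch and Wnt pathway genes, 2 rose, 12 fell and 14 did not pass, and adjusted over the list alone, 2 passed higher and 14 lower. Without wild-type replicate 3 or knock-in replicate 3, 7 fell, and without wild-type replicate 2 or 3, 1 rose. The genes that fell included Lef1 (-1.37), a Wnt effector of the hair matrix, and Notch1 (-0.69). Notch and Wnt genes had a median log2 difference of -0.37 (camera adjusted p = 0.00289, and adjusted p = 0.620 with an estimated correlation), and fry gave adjusted p = 0.0541, in a range from 2.61e-04 to 0.620 with an estimated correlation over 20 alternatives. Of 13 melanocyte genes, 0 rose, 8 fell and 5 did not pass, and adjusted over the list alone, 0 passed higher and 9 lower. The pigment cell genes Mlana and Tyr, the rate-limiting enzyme of melanin synthesis, fell from 323 ± 122 and 272 ± 121 to 59.4 ± 33.4 and 69.9 ± 26.0 (-2.20 ± 0.32 and -1.71 ± 0.29). Melanocyte genes had a median log2 difference of -1.05 (camera adjusted p = 0.000572, and adjusted p = 0.432 with an estimated correlation). Without wild-type replicate 1 their median was -0.62 (camera adjusted p = 0.00125, in a range from 1.11e-04 to 0.432 with an estimated correlation over 20 alternatives). Sebaceous gland genes did not pass (camera adjusted p = 0.267). They counted 5 higher and 4 lower of 22 (6 and 5 when adjusted over the list alone). Cyp2g1 (3.63), Elovl3 (1.64) and Plin2 (1.45) were higher while Prdm1 (-0.73) was lower.

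Lists of mast cell, macrophage and type 2 response genes were higher. Of 9 mast cell, basophil and eosinophil genes, 7 rose, 0 fell and 2 did not pass, and adjusted over the list alone, 8 passed higher and 0 lower. The mast cell tryptase Tpsab1 rose from 15.5 ± 4.30 to 644 ± 70.0 (4.39 ± 0.14) and the IgE receptor subunit Fcer1a from 42.9 ± 11.4 to 466 ± 26.5 (3.05 ± 0.15). Mast cell, basophil and eosinophil genes had a median log2 difference of 1.69 (camera adjusted p = 2.34e-07, and adjusted p = 0.178 with an estimated correlation). The filter kept 9 of the 18 on the array, and without it the median was 0.53. Of 23 macrophage and monocyte genes, 13 rose, 1 fell and 9 did not pass, and adjusted over the list alone, 15 passed higher and 1 lower. Without wild-type replicate 3 or knock-in replicate 3, 8 rose, and without wild-type replicate 1 and 2, 2 and 0 fell. The endotoxin co-receptor Cd14 rose from 139 ± 32.9 to 2874 ± 832 (4.20 ± 0.23) and the haemoglobin scavenger receptor Cd163 by 2.70 ± 0.27. Macrophage and monocyte genes had a median log2 difference of 0.77 (camera adjusted p = 2.72e-05, and adjusted p = 0.604 with an estimated correlation), and fry gave adjusted p = 0.0591, in a range from 1.42e-08 to 0.604 with an estimated correlation over 20 alternatives. Of 13 type 2 response genes, 10 rose, 1 fell and 2 did not pass (10 rose and 1 to 2 fell with an array left out), and adjusted over the list alone, 10 passed higher and 2 lower. Il33, an epithelial alarmin, rose from 134 ± 13.2 to 872 ± 255 (2.53 ± 0.19) and the receptor chains Il4ra and Il13ra1 by 1.57 ± 0.12 and 1.08 ± 0.11. Type 2 genes had a median log2 difference of 1.36 (camera adjusted p = 2.72e-05, and adjusted p = 0.258 with an estimated correlation). The filter kept 13 of the 24 on the array, and without it the median was 0.29.

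Lists of MHC class II and of B and plasma cell genes were lower. Of 8 genes of MHC class II presentation, 1 rose, 6 fell and 1 did not pass, and adjusted over the list alone, 1 passed higher and 6 lower. H2-Aa fell from 3880.2 ± 1021 to 1057 ± 216 (-1.84 ± 0.21), H2-Eb1 from 2590.2 ± 708 to 546 ± 138 (-2.20 ± 0.23) and the invariant chain Cd74 had a difference of -1.90 ± 0.24. The member that rose was Ctss, a lysosomal protease, named after its value was seen (1.02). MHC class II genes had a median log2 difference of -1.60 (camera adjusted p = 0.00549, and adjusted p = 0.600 with an estimated correlation). Of 12 B and plasma cell genes on the array, 3 passed the filter on dim probe sets. These 3 fell, also when adjusted over the list alone, and were Blnk (-1.19) and the immunoglobulin heavy chains Ighm (-1.17, or -1.84 without shared probe sets) and Igha (-1.83, or -2.96). B and plasma cell genes had a median log2 difference of -1.19 (camera adjusted p = 0.00304, and adjusted p = 0.258 with an estimated correlation), and their median was -0.44 with no filter and -1.84 without shared probe sets. Dendritic and Langerhans cell genes did not pass, with 3 higher and 5 lower of 11 (3 and 5 when adjusted over the list alone, 3 and 3 to 5 with an array left out, camera adjusted p = 0.365), where the Langerhans cell lectin Cd207 (-1.59) and Mgl2 (-2.28) fell and Fscn1 (0.89, or 0.51 with the mean over its probe sets) rose. T and NK cell genes, of which 7 of 27 on the array passed the filter, did not pass the list test, with 0 higher and 2 lower of 7 (0 and 2 when adjusted over the list alone, camera adjusted p = 0.204), of which Cd3g (-1.66) and Nkg7 (-1.18) fell and Cd8a had a difference of -0.13 ± 0.15. Interferon-stimulated genes did not pass, with 1 higher and 4 lower of 27 (1 and 4 when adjusted over the list alone, 0 to 3 and 3 to 6 with an array left out, camera adjusted p = 0.227), and without wild-type replicate 1 their camera adjusted p was 0.0395, in a range from 0.0395 to 0.832 with an estimated correlation over 20 alternatives. Psmb9 (-0.84) and Usp18 (-0.79) were among those that fell, and Xaf1 (-1.42) had the opposite sign when its 2 probe sets were averaged (0.87, adjusted p = 0.00193), in a range from 3.81e-04 to 0.00543 over 19 alternatives.

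**Figure D2:**
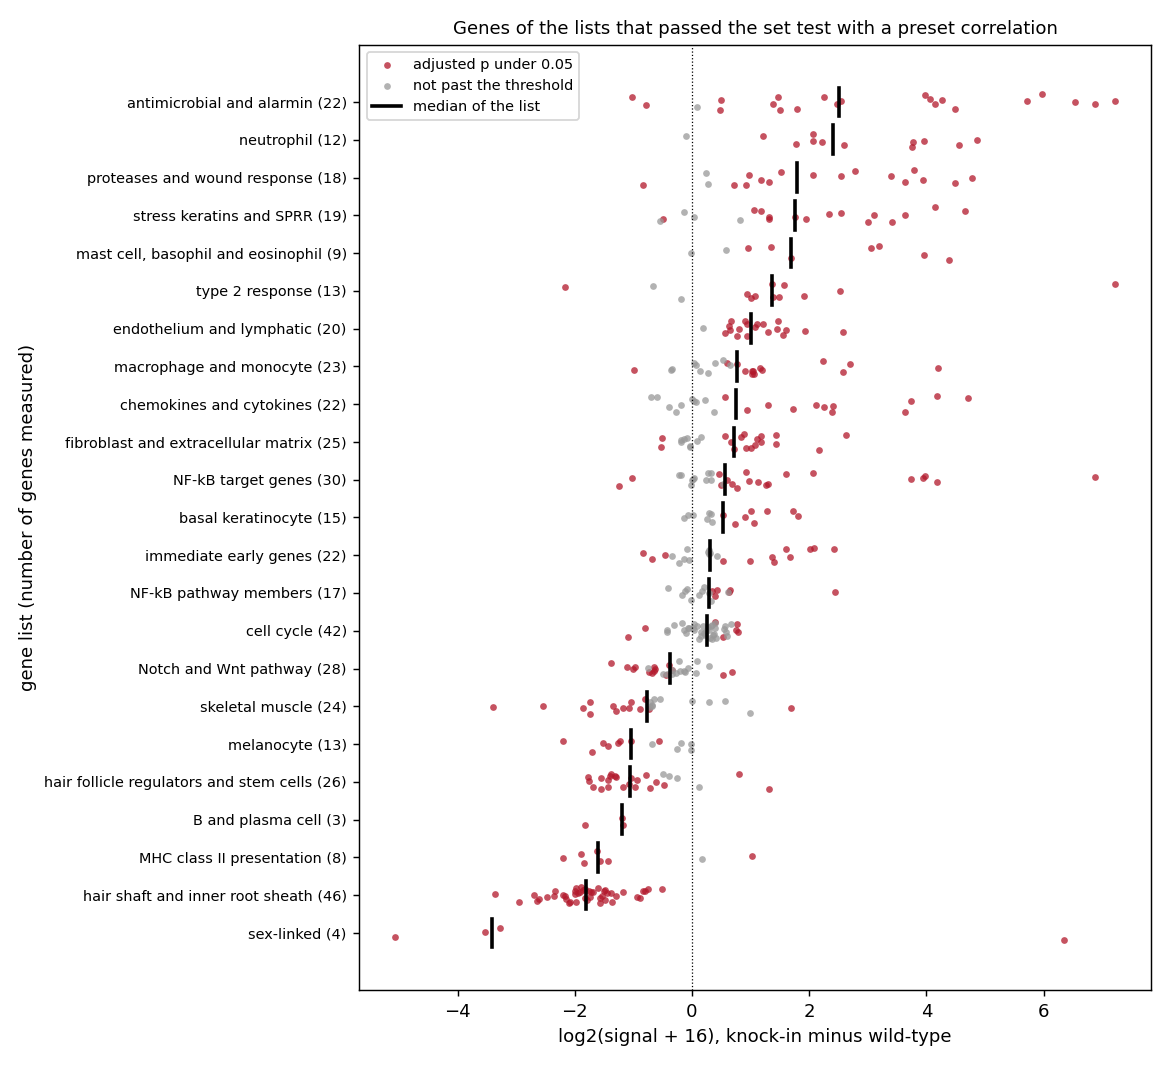
Log2 difference (knock-in minus wild-type, log2(signal + 16) scale) of each measured gene in the 23 lists that passed camera at the preset correlation, with 1 point per gene, red where its adjusted p is under 0.05, and a black bar at the list's median. The medians run from -3.41 for the sex-linked list, which joins Xist with Y-linked genes, to 2.51 for the antimicrobial list, and all hair shaft genes lie below 0.

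Lists of endothelial and fibroblast genes were higher and the skeletal muscle list lower. Of 20 endothelial and lymphatic genes, 19 rose, 0 fell and 1 did not pass, and adjusted over the list alone, 19 passed higher and 0 lower. Pecam1, an adhesion molecule of endothelial junctions, rose from 114 ± 16.8 to 342 ± 29.3 (1.47 ± 0.13), Emcn by 1.92 ± 0.12 and Lyve1, which lymphatic vessels and some macrophages share, by 2.58 ± 0.14. Endothelial genes had a median log2 difference of 1.01 (camera adjusted p = 3.06e-12, and adjusted p = 0.236 with an estimated correlation). Of 25 fibroblast and matrix genes, 15 rose, 2 fell and 8 did not pass (13 to 15 rose and 0 to 2 fell with an array left out), and adjusted over the list alone, 15 passed higher and 2 lower. Pdgfra rose from 452 ± 49.0 to 1254 ± 119.8 (1.44 ± 0.11), the Wnt modulator Sfrp2 by 2.62 ± 0.19 and the fibrillar collagen Col5a2 by 1.11 ± 0.14. Fibroblast genes had a median log2 difference of 0.72 (camera adjusted p = 7.08e-05, and adjusted p = 0.452 with an estimated correlation). Of 24 skeletal muscle genes, 1 rose, 13 fell and 10 did not pass, and adjusted over the list alone, 2 passed higher and 16 lower. Without knock-in replicate 3, 8 fell, and without wild-type replicate 3 and knock-in replicate 2, 0 and 3 rose. Myh4, a fast myosin, fell from 8475 ± 2157 to 2473 ± 329 (-1.75 ± 0.18), and Casq1 and Mybpc2 had differences of -2.54 and -1.86. The member that rose was the slow troponin Tnnt1, named after its value was seen (1.69), which without wild-type replicate 3 was at 1.40 and did not pass (adjusted p = 0.0669, and from 0.00306 to 0.047 with another array left out). Muscle genes had a median log2 difference of -0.76 (camera adjusted p = 0.000174, and adjusted p = 0.676 with an estimated correlation), and fry gave adjusted p = 0.0963, in a range from 1.87e-08 to 0.676 with an estimated correlation over 20 alternatives. Smooth muscle and pericyte genes did not pass, with 2 higher and 3 lower of 11 (2 and 3 when adjusted over the list alone, 1 to 2 and 1 to 3 with an array left out, camera adjusted p = 0.631), and Rgs5 was at 1.10 and Smtn at -0.74. Adipocyte genes did not pass, with 3 higher and 2 lower of 15 (3 and 2 when adjusted over the list alone, 2 to 4 and 1 to 4 with an array left out, camera adjusted p = 0.454), and Pck1 was at 1.16 and Lpl at -0.44. Schwann cell and nerve genes did not pass, with 2 higher and 2 lower of 9 (2 and 3 when adjusted over the list alone, 1 to 2 and 2 to 3 with an array left out, camera adjusted p = 0.814), and Mbp was at -1.07, or -0.62 with the mean over its probe sets, and Scn7a at 0.96. Erythroid genes did not pass, with 2 higher and 2 lower of 6 (2 and 3 when adjusted over the list alone, camera adjusted p = 0.752), where Alas2 (1.27) was higher and Hba-a2 (-1.04) lower, and the median (-0.16, from -0.21 to -0.09 with an array left out) and mean (0.01) differed in sign.

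Of 22 immediate early genes, 9 rose, 3 fell and 10 did not pass, and adjusted over the list alone, 11 passed higher and 4 lower. Fos rose from 284 ± 42.7 to 1195 ± 175 (2.01 ± 0.14), Socs3, a feedback inhibitor of cytokine signalling, from 162 ± 27.6 to 935 ± 139 (2.42 ± 0.15), and Dusp1 by 2.07 ± 0.19. Immediate early genes had a median log2 difference of 0.31 (camera adjusted p = 0.00503, and adjusted p = 0.258 with an estimated correlation). With a stricter filter their camera adjusted p was 0.117, in a range from 7.08e-04 to 0.258 with an estimated correlation over 20 alternatives. Of 42 cell cycle genes, 5 rose, 2 fell and 35 did not pass, and adjusted over the list alone, 3 passed higher and 2 lower. Those that rose numbered 17 without wild-type replicate 1, 3 without 2 and 0 without 3, and 2 without knock-in replicate 2 or 3. Ccnd1, the G1 cyclin, fell (-1.09 ± 0.16), while Birc5 was at 0.79 ± 0.18 and Rrm2 at 0.78 ± 0.20, both no longer past the threshold without wild-type replicate 3 (adjusted p = 0.053 and 0.0637, each the highest over their alternatives). Cell cycle genes had a median log2 difference of 0.26 (camera adjusted p = 0.0288, and adjusted p = 0.821 with an estimated correlation), and their median was 0.44 without wild-type replicate 1 and 0.15 without 2. They did not pass without wild-type replicate 2 (0.364) or 3 (0.111), without knock-in replicate 2 (0.144) or 3 (0.112), with a stricter filter (0.082) or with fry (0.5), in a range from 1.94e-05 to 0.821 with an estimated correlation over 20 alternatives.

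Among the genes of the circadian clock, some rose and others fell, and the list as a whole did not pass, with 4 higher and 6 lower of 15 (5 and 6 when adjusted over the list alone, camera adjusted p = 0.528). Without knock-in replicate 1, 2 were higher. Dbp, an output gene of the clock, fell from 1049 ± 299 to 113 ± 15.5, a log2 difference of -3.01 ± 0.20 (adjusted p = 3.51e-05). Per3 and Nr1d2 had differences of -1.32 ± 0.18 and -1.05 ± 0.17. Clock itself rose from 210.5 ± 33.4 to 363 ± 23.1 (0.75 ± 0.12), but with the mean over its probe sets the difference was 0.28 (adjusted p = 0.0802, in a range from 0.00136 to 0.0802 over 19 alternatives).

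**Figure D3:**
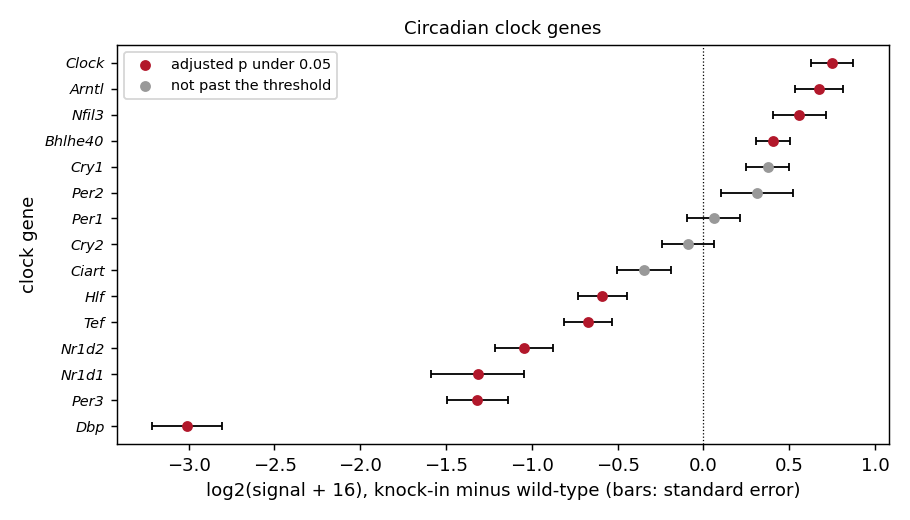
Log2 difference (knock-in minus wild-type, log2(signal + 16) scale) of 15 clock genes, with 1 point per gene and bars of 1 standard error, red where the adjusted p is under 0.05. Differences run from -3.01 for Dbp to 0.75 for Clock.

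The remaining lists did not pass. NRF2 target genes counted 8 higher and 5 lower of 22 (9 and 6 when adjusted over the list alone, camera adjusted p = 0.124), with the glutathione transferases Gsta4 (3.67) and Gsta2 (-1.57) in opposite directions, and fry gave adjusted p = 0.00432, in a range from 0.00432 with fry to 0.364 with an estimated correlation over 20 alternatives. Lower NRF2 targets numbered 2 without wild-type replicate 1 or 3 or knock-in replicate 1, and 3 without knock-in replicate 3. TGF-beta pathway genes counted 6 higher and 5 lower of 21 (6 and 6 when adjusted over the list alone, camera adjusted p = 0.45), with Inhba at 1.93 and Tgfb2 at -1.33, and fry gave adjusted p = 0.029, in a range from 0.0290 with fry to 0.821 with an estimated correlation over 20 alternatives. Lower TGF-beta genes numbered 2 without wild-type replicate 3 or knock-in replicate 1, and 3 without wild-type replicate 1 or knock-in replicate 3. Heat shock and unfolded protein genes counted 4 higher and 4 lower of 20 (5 and 4 when adjusted over the list alone, camera adjusted p = 0.432), with Hspa1a at -0.66 and Atf4 at 0.47, or 0.26 and not past the threshold with the mean over its probe sets (adjusted p = 0.0752, in a range from 0.00263 to 0.0752 over 19 alternatives). The heat shock list counted 2 higher without wild-type replicate 1, 1 lower without wild-type replicate 3, and 1 higher and 1 lower without knock-in replicate 3. Genes of p53, senescence and CDK inhibition counted 3 higher and 3 lower of 22 (3 and 3 when adjusted over the list alone, camera adjusted p = 0.984), with Pmaip1 at 0.94 and Cdkn1c at -0.86. The p53 list counted 1 higher without wild-type replicate 1 or knock-in replicate 1 or 3, and 1 lower without wild-type replicate 3 or knock-in replicate 1. Cholesterol synthesis genes counted 2 higher and 1 lower of 18 (2 and 1 when adjusted over the list alone, 2 to 3 and 1 to 2 with an array left out, camera adjusted p = 0.617), with Idi1 at 1.20 and Insig1 at -0.96. Respiratory chain genes counted 0 higher and 1 lower of 35 (0 and 0 when adjusted over the list alone, 0 to 2 and 1 with an array left out, camera adjusted p = 0.751), with Ndufb8 at -0.38, or -0.07 and not past the threshold with the mean over its probe sets (adjusted p = 0.581, in a range from 0.00369 to 0.581 over 19 alternatives).

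Of the 42 lists, 23 passed camera at the preset correlation, 15 higher and 8 lower, and the smallest adjusted p with an estimated correlation was 0.137. The 8 lower lists include the sex-linked list, whose direction reflects only its make-up. For all genes named with a direction, the 3 knock-in values lay on one side of the 3 wild-type values, unlike those of Cd8a. The rule for the largest differences required this, and list members were named by their smallest p, so it adds no support. Of all genes tested, 47.0% lay so. The p-values of gene lists depend on how strongly the genes of a list vary together, which 6 arrays estimate poorly.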

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

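The tests on exchanged samples, on sex across all genes, on hair follicle genes and on clock genes were chosen after the results were seen, and those on other splits of the arrays and on genes that escape X inactivation before.

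Signals outside the genes of the report also differed between the groups. Probe sets that name no gene gave 272 higher and 689 lower in knock-in past the threshold of 2904 tested (33.1%), of which 13 were at least 8-fold higher. The 3' control for Gapdh was higher on all 3 knock-in arrays, with a knock-in mean of 1.24 times the wild-type mean (4554 and 5648). The control for B1 repeats, short interspersed elements found in many transcripts, was higher by 1.28 times (2061 and 2628). The 5' and middle Gapdh controls overlapped between the groups. Other controls were lower on all 3 knock-in arrays. These were the 5' and middle 18S controls (0.260 and 0.473 times) and the middle control for the transferrin receptor (0.569 times, at dim means of 17.0 and 9.67). For a single feature, chance puts all 3 arrays of a given group above all of the other in 1 of 20 cases.

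Genotype and the sex-linked pattern separated the arrays in the same way. Genes that escape X inactivation had a median log2 difference of 0.3415 (0.2508 to 0.4325, 95% bootstrap over 7 genes that are not independent), which is consistent with male wild-type and female knock-in animals. After an exchange of single samples between the groups, an exchanged array would resemble the other group. Pearson's r was 0.975 or above within the groups and 0.917 or below between them. In addition, 0 of 6 arrays had the other group's level of Xist or a Y-linked gene. This count only restates the sex-linked pattern and decides nothing. The correlations argue against an exchange of single samples, provided that the genotypes differ in expression. A sex difference in the whole transcriptome cannot be told apart from genotype, because 0 arrays break the pattern. Of the 10 splits of the arrays 1 gave as many genes, the real one with 3625 against 0 for the highest other, and 10 splits are too few for a share under 0.05.

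Lower hair shaft genes were set against dilution by other cells, loss of whole follicles with their glands and another stage of the hair cycle. The median of hair shaft genes lay -1.687 (-2.015 to -1.327) from that of suprabasal genes. Intervals here are 95% bootstraps over genes that are not independent, so they do not measure the spread between samples. With an array left out, the hair shaft median ranged from -2.09 to -1.484 and the suprabasal median from -0.1528 to -0.04155. These values argue against a dilution that lowers both lists alike. A rise of suprabasal genes that hides a dilution was not tested. The median of sebaceous gland genes was 0.1451 (-0.08841 to 0.517). With an array left out it ranged from 0.08608 without wild-type replicate 3 to 0.2309 without wild-type replicate 2. With 5 higher and 4 lower of 22, the genes of that list did not fall together with the hair shaft genes. Whether they mark the gland alone was not tested, so loss of whole pilosebaceous units stays open. Another stage of the hair cycle may account for the pattern and stays open, since matrix regulators minus stem cell genes gave -0.6469 (-1.141 to 0.1203), an interval that includes 0. An effect of the genotype on the follicle, and the sex of the animals, stay open and were not tested apart.

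Clock genes were both higher and lower in knock-in. A loss of clock signal with the share of another cell type would lower them together. Of 15, 4 were past the threshold and higher (2 without knock-in replicate 1, the fewest with an array left out), although Clock did not pass with the mean over its probe sets. This argues against such a loss as the whole cause, but not against a change in cell shares that also adds cells. Another time of day at collection cannot be told apart from genotype, because the labels give no time. Genes that peak with Arntl minus those that peak with Dbp gave 1.774 (1.245 to 2.455, 95% bootstrap over 11 genes that are not independent). These sets were chosen after the values were seen and leave out Per1, Per2, Bhlhe40 and Cry2, so the value decides nothing. An effect of the genotype on the clock stays open too.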

How the results depend on the processing

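Leaving out the X- and Y-linked genes was chosen after the data were seen. Of the counts under all alternatives, 91 stayed within 1.5 times the main value and 6 did not. Results for gene lists kept direction and side of the threshold in 777 cases, lost the call in 36, gained it in 7 and turned in 17. For named genes these were 3210, 50, 8 and 1. With quantile normalization 3321 of the 3625 calls were kept. With an offset of 64, genes past the threshold and at least 2-fold numbered 600, as a larger offset shrinks folds. With all 23127 probe sets tested, 7007 passed (30.3%), since more features were tested. With an estimated inter-gene correlation 0 gene lists passed, where camera at the preset correlation gave 23 and fry 21. The robust variance prior has no list test.

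With each array left out in turn, genes past the threshold ranged from 2369 to 3353 and genes lower in knock-in from 1215 to 1744, the lowest without wild-type replicate 3. With the replicate block, 2439 genes passed, and genes lower in knock-in numbered 1258, against 3625 and 1900. No sample correlated best with the sample of its own number (r = -0.25, -0.41 and -0.0150), so the numbers were not used as pairs.

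The direction of the list test turned only for lists that did not pass, and the cause was not tested. This direction is that of camera, which compares a list with all other genes, so the sign of the median need not turn. The medians were 0.03401 for Schwann cell and nerve and 0.03423 for EGFR ligands and receptors with no filter. With the stricter filter they were 0.5064 for dendritic and Langerhans cell, 0.04802 for erythroid (blood) and -0.03507 for p53, senescence and CDK inhibitors. The p53 list also turned with quantile normalization (-0.03603), array weights (-0.006672) and shared probe sets left out (-0.02554). The EGFR list turned with the mean over probe sets (0.1008). For smooth muscle and pericyte the direction turned with shared probe sets left out, although the median kept its sign (-0.06808, against -0.186). The same held for the adipocyte list without wild-type replicate 1 (0.07667) and the EGFR list without knock-in replicate 3 (-0.07807). With an array left out, medians ranged over 0.0371 to 0.1687 for adipocyte, -0.1281 to 0.1129 for Schwann cell genes, -0.05673 to 0.01453 for the p53 list, -0.1527 to -0.04576 for the EGFR list and -0.2138 to -0.08997 for erythroid genes. Xaf1 turned with the mean over its probe sets (0.8672, against -1.42), and the cause was not tested.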

Other observations

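All tests here were chosen after the results were seen. The gene groups of the next paragraph were also put together after values of their members had been seen, so they carry no p-value and their counts describe only the genes chosen.

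Of 14 glucocorticoid-responsive genes, 13 were past the threshold and higher in knock-in (median log2 difference 1.28), among them Fkbp5 (2.45), Pdk4 (2.51) and the metal-binding Mt1 (1.91), while Per1 did not pass (0.06). Of 11 acute phase genes, 10 were higher (median 2.73), such as Serpina3n (3.39) and Ptx3 (3.21), and Orm1 did not pass (-0.08). Of 10 glucose uptake and hypoxia genes, 9 were higher (median 0.72), with the glucose transporters Slc2a1 (2.33) and Slc2a3 (2.11) among them. Of 11 fast muscle fibre genes, 10 were lower (median -1.75). Of 9 genes of slow or stressed fibres, 7 were higher (median 1.69), such as Ankrd2 (3.27) and Csrp3 (2.98), and without wild-type replicate 3 the number was 4. All 37 measured Krtap genes were lower (median -2.11).

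Ifi202b, an interferon-inducible gene, was higher in all 3 knock-in samples, at a log2 difference of 4.04 (mean signal 56.9 in wild-type and 1316 in knock-in, adjusted p = 1.08e-04). A general interferon response could raise it, but the median of interferon-stimulated genes was -0.1701 (-0.3591 to 0.03111, 95% bootstrap over 27 genes that are not independent, and with an array left out from -0.3131 without wild-type replicate 1 to -0.05789 without wild-type replicate 2), which argues against that. A difference in genetic background near this gene was not tested.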
